A study of Mus musculus with 4 samples.

How the data were processed

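NK cells and T cells were sorted from subcutaneous CT26 tumours of BALB/c mice. Per the labels' protocols, each injection held 500000 live tumour cells in 200 uL of saline. Tumours were broken up mechanically, filtered (70 um), enriched for immune cells by Percoll centrifugation and sorted, and libraries were made from total RNA with standard Illumina methods. The sort gate is not given in the sources used here. The submitters' processing notes name FastQC, Bowtie2 2.3.4.1, STAR 2.7.0f, limma and the genome build GRCm38.p6, without their roles. The counting tool, the strand setting and the normalization are not given in the sources used here.

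The deposited values are a normalized signal, per the file headers 1 column per library, for 55450 genes. In the values themselves, every non-zero entry was a whole multiple of the library's smallest non-zero value within a tolerance of 0.001 reads, in 100% of cases. The whole reads recovered in this way totalled 2228226 and 2665928 for NK pools 1 and 2, and 2067728 and 2893240 for T pools 1 and 2. The implied library scaling factors were 1.103, 1.058, 0.8782 and 0.9754, and TMM factors recomputed from the recovered reads were equal to them at the 4 digits compared. The deposited signal is therefore treated as read counts per 1 M of TMM-scaled library size (normalized CPM), with no correction for gene length. Rows without a gene name in the deposited table took 0.02% to 0.021% of reads. All 55450 identifiers were found in the GENCODE M21 annotation of GRCm38, which supplied coordinates, and 27 symbols that a spreadsheet had turned into dates were restored from a gene name table. No pair of libraries agreed within sampling noise (chi-square per degree of freedom 11.3 to 37.1).

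Genes with a mean of at least 1 normalized CPM were tested, 12128 in all. For rows sharing a symbol the row with the highest mean was kept. Values were transformed as log2(value + 1) and tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend in the spread, 2 residual degrees of freedom), NK minus T, with Benjamini-Hochberg adjustment at 0.05. Linear values were allowed for when the design was fixed, so the planned test applied. For 36 gene lists, members past the threshold were counted, over all genes and adjusted over the list alone. Some are identity lists, which hold genes that define the cells, and their calls describe the sort. Lists of function and programme genes share members with them, such as Gzma, Gzmb, Prf1, Xcl1, Cd244a, Klrg1, Cd5, Icos, Tnfrsf4, Cd40lg, Eomes and Itga1. Calls of these shared members also describe the sort. The 32 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. None of the camera calls held with the estimated correlation (lowest adjusted p = 0.157). Groups, gene lists, main test, alternative settings (except those named at the end) and the rule for named genes were chosen before the data were examined. That rule takes the 12 genes with the largest log2 fold change per direction among those past the threshold with non-overlapping values and a higher group mean of at least 10, leaving out unnamed gene models, pseudogenes and receptor segments. It adds up to 4 members per list past the threshold (2 per direction where both occur), or the 2 most abundant where none passed, and 8 genes that check the labels (Cd3e, Cd3g, Trac, Cd8a, Cd4, Ncr1, Klrb1c and Eomes). A gene that this rule named is not reported here. Exons of Klrb1c, Avil, Serpinb9b, Ramp3, Themis, Cd3e, Eomes, Trdc, Itga1, Xcl1, Plcg1, Lat, Spp1, Itgam, Cd9, Fn1, Ifi47, Top2a, Cox5a and Il1b, among the genes that this rule named and the text gives, overlap another annotated gene. Where the other gene lies on the opposite strand, reads are not fully separable without a stated strand setting. Where it lies on the same strand, as for Klrb1c, Itga1, Lat and Spp1, a strand setting would not separate them either.

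The replicate number was taken to pair the NK and T libraries, because the series' design text ties each number to a pool of mice. Across genes, the difference between the NK pools correlated with the difference between the T pools at 0.161. The fit without the block was kept as the main test because no source states that the study's model had it. The fit with the replicate block has 1 residual degree of freedom. Its p-values rest on spread shared across genes and hardly on a gene's own spread. Counts with the replicate block are therefore given as a comparison and not as support for the main fit.

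Ratios over recovered reads have exact 95% binomial intervals. A gene with 0 reads in a group is given a lower bound of its fold against 3 reads over that group (0.568 normalized CPM for NK cells and 0.647 for T cells). The test was checked on simulated counts with 200 genes changed per draw over 5 draws (median 11567 genes tested). Limma recovered 54.4% of genes changed 4-fold, 90.0% of those changed 8-fold and 99.6% of those changed 16-fold, and 5.71% of its calls were false. The changed genes were drawn from those with a mean of at least 10 normalized CPM. The simulated counts held no effect of pool and no RNA of other cells. These rates therefore do not cover lower genes, pool differences or such RNA. A count test, edgeR 4.0.16 (quasi-likelihood), and DESeq2 1.42.0 were run on the recovered reads as alternatives. Other alternatives changed the filter, pseudocount, normalization, spread model, set test, and libraries used. A macrophage score covariate, removal of ribosomal RNA genes, edgeR with the replicate block, limma-voom and edgeR without each library in turn were added after the data were seen. Figures were drawn with matplotlib 3.10.9.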

Results

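RNA sequencing was used to profile natural killer (NK) cells and T cells sorted from subcutaneous CT26 tumours, a colon carcinoma line, grown in syngeneic BALB/c mice. The 4 libraries fall into 2 groups, NK cells and T cells, with 2 libraries each. Replicate 1 of each cell type was pooled from 4 mice and replicate 2 from 6 mice, so a replicate is a pool of mice. The limma p-values rest on 2 pools per cell type and on spread borrowed across genes, not on each gene's own spread alone. The comparison asks which genes differ between the NK cells and the T cells of the same kind of tumour. The NK libraries of pools 1 and 2 held 2228226 and 2665928 gene-assigned reads, and the T libraries 2067728 and 2893240. Ribosomal RNA genes, namely Gm42418 (a gene model that overlaps a ribosomal RNA repeat), mt-Rnr1 and mt-Rnr2, took 36.9% and 38.8% of the NK reads and 52.4% and 42.7% of the T reads. Values are given as TMM-scaled counts per 1 M reads (normalized CPM) unless another unit is named. A single read was worth 0.407, 0.355, 0.551 and 0.354 normalized CPM in the same order of libraries. Counting intervals and floors cover counting error only. Log2 fold changes are NK minus T on the log2(value + 1) scale, which understates the change of low genes.

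The NK cells carried higher levels of cytotoxic effector and NK receptor genes. The T cells carried higher levels of T cell receptor complex genes and of the coreceptor genes Cd8a and Cd4. Of 12128 genes tested, 150 were higher in NK cells and 132 higher in T cells (limma, Benjamini-Hochberg adjusted p under 0.05). In all 282 the 2 NK values lay apart from the 2 T values, which held for 43.4% of all genes tested, against 33.3% by chance. The median absolute log2 fold change of the 282 genes was 3.42, and the smallest was 1.31. With the pool of mice as a replicate block the count rose to 999 genes, 517 higher in NK cells and 482 higher in T cells, and these included all 282. That fit has 1 residual degree of freedom. The rise need not mean less spread, since Id2, for example, had an SE of 0.285 without the block and 0.297 with it. Its limma adjusted p nonetheless fell from 0.0379 to 2.62e-04. With any library left out limma called 0 genes (752 to 1759 at an unadjusted p under 0.05), while edgeR called 324 genes on all libraries and 330 to 514 without each in turn.

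Gzma, which encodes the serine protease granzyme A, showed the largest difference on the log2(value + 1) scale, but not as a ratio of reads (412, counting interval 333 to 516). It reached 7627 ± 1459 (SD, n = 2) in NK cells against 16.5 and 19.5 in the 2 T libraries, a log2 fold change of 8.64 (SE 0.30, limma adjusted p = 3.17e-07). Its gene (ENSMUSG00000023132.8) lies on the minus strand of chromosome 13 at 113093825 to 113100981 (GRCm38). Ncr1, the activating receptor NKp46, on chromosome 7 at 4337724 to 4345164, stood at 516 ± 212 against 0.71 ± 1.00, with a log2 fold change of 8.31 (SE 0.54, limma adjusted p = 4.54e-05). Klrb1c, which encodes an activating NK cell lectin-like receptor, had 696 reads in NK cells and 1 read in T cells, a ratio of 612 with a counting interval of 109 to 24200. Klrb1f (log2 fold change 6.12, SE 0.56), Klra3 (6.04, SE 0.63) and Klri2 (5.66, SE 0.83), further lectin-like receptors, were also higher in NK cells. Their values in T pools 1 and 2 were 1.65 and 0.35 for Klrb1f, 0 and 2.48 for Klra3 and 0 and 8.15 for Klri2, so the sizes of these folds differ with the T library used. Gzmc, another granzyme, reached 1088 ± 49.9 against 6.61 and 41.5 in the T libraries. Tmsb15a, a thymosin of the actin-binding family, and Avil, an actin-regulating protein of the villin family, had 0 reads in both T libraries. Against a floor of 3 reads over the T group they were at least 267-fold and at least 77.6-fold higher in NK cells. Car2, a carbonic anhydrase, stood at 561 ± 121 against 13.6 ± 11.4. Rab27b, a small GTPase of secretory vesicles, had 269 reads in NK cells and 1 in T cells (ratio 236, counting interval 42.1 to 9370). Serpinb9b, a serpin of the granzyme inhibitor family, was higher by a log2 fold change of 5.46 (SE 1.12, limma adjusted p = 0.0311), with 0 and 25.5 in the T libraries.

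**Figure D1:**
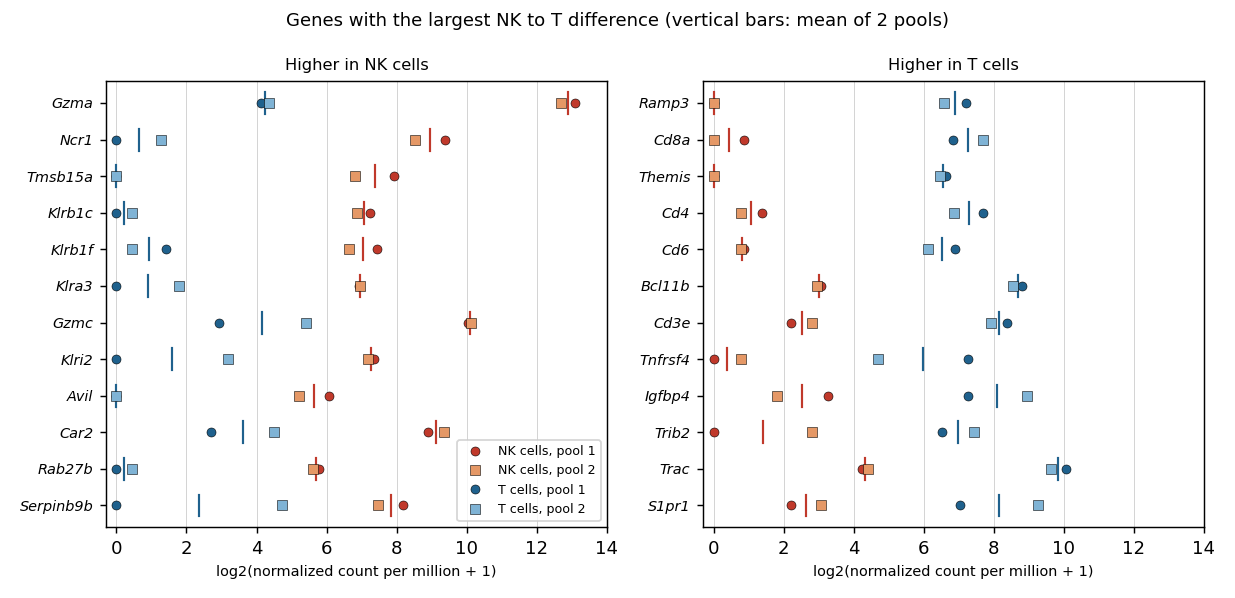
Values of the 12 genes with the largest log2 fold change in each direction, as log2(normalized CPM + 1) on the horizontal axis. Each point is 1 library and each vertical bar the mean of the 2 pools of a cell type. NK and T points are apart for every gene shown, and Gzma lies at 8659 and 6595 in NK cells against 16.5 and 19.5 in T cells.

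On the T cell side, Ramp3, a receptor activity-modifying protein, on chromosome 11 at 6658521 to 6677475, had 0 reads in both NK libraries and was at least 202-fold higher in T cells, against a floor of 3 reads over the NK group. Themis, a T cell signalling protein, likewise had 0 NK reads and was at least 162-fold higher. Cd8a (159 ± 64.1 in T cells) had 2 reads in NK cells, a T to NK ratio of 445 with a counting interval of 123 to 3680. Cd4 stood at 162 ± 63.6 in T cells against 1.17 ± 0.65 in NK cells. Bcl11b, a transcription factor of T cell commitment, reached 410 ± 47.1 against 7.03 ± 0.41 (log2 fold change -5.67, SE 0.36, limma adjusted p = 4.54e-05), and Trac, the T cell receptor alpha constant region, 929 ± 196 against 19.1 ± 1.64. Cd3e, which encodes a CD3 chain, reached 287 ± 66.1 against 4.84 ± 1.67. Cd6, a T cell adhesion receptor, Igfbp4, Trib2 and S1pr1, the receptor for egress along sphingosine 1-phosphate, differed by log2 fold changes of -5.70 (SE 0.55), -5.58 (SE 0.62), -5.56 (SE 0.80) and -5.50 (SE 0.65). In T pools 1 and 2 Igfbp4 stood at 154 and 489, Trib2 at 90.3 and 171, and S1pr1 at 129 and 615, so the sizes of their folds differ between pools. Tnfrsf4, the costimulatory receptor OX40, had 2 NK reads and a T to NK ratio of 199 (counting interval 54.6 to 1650), with 153 in T pool 1 and 25.2 in T pool 2.

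Genes past the threshold in the T cell receptor, CD4 and NK identity lists followed the labels, and they describe the sort. Genes of the CD8 and gamma-delta lists went both ways. Of 18 measured T cell receptor and CD3 complex genes, 14 were higher in T cells and 0 in NK cells (16 adjusted over the list alone), with camera adjusted p = 3.41e-32 and adjusted p = 0.157 with an estimated correlation. Cd3g differed less than Cd3e, at 25.1 ± 14.5 in NK cells and 187 ± 75.7 in T cells (limma adjusted p = 0.00937). Trbc1, a beta chain constant region named after its values were seen, stood at 205 and 211 in NK cells against 282 and 406 in T cells (limma adjusted p = 0.383). Of 14 CD4 helper and regulatory genes, 8 were higher in T cells and 0 in NK cells (10 adjusted over the list alone), among them Cd40lg and Izumo1r, each with 0 NK reads and at least 78.5-fold and at least 41.7-fold higher. For this list camera gave adjusted p = 3.94e-13, and adjusted p = 0.352 with an estimated correlation. In the CD8 list of 6 genes, Cd8a and Cd8b1 were higher in T cells and Eomes, a T-box factor also of NK cells, was higher in NK cells at 356 ± 103 against 26.8 ± 8.26 (2 and 2 adjusted over the list alone). This list's median log2 fold change was 0.37 and its mean -1.04, and camera gave adjusted p = 0.706. Of 7 gamma-delta markers, Trdc alone passed, at 279 ± 8.86 in NK cells against 45.9 ± 32.4 in T cells (2 and 2 adjusted over the list alone, and 2 and 2 with the replicate block; camera adjusted p = 0.832).

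Of 27 measured NK identity genes, 19 were higher in NK cells and 0 in T cells (25 adjusted over the list alone), with camera adjusted p = 2.91e-38 and adjusted p = 0.157 with an estimated correlation. Of 10 genes of the Ly49 family of class I-sensing receptors, 5 were higher in NK cells and 0 in T cells (8 adjusted over the list alone; camera adjusted p = 4.25e-12, and adjusted p = 0.185 with an estimated correlation). Klra3, Klra7, Klra13-ps and Klra9 had log2 fold changes of 6.04, 4.83, 4.80 and 4.46. Klra13-ps is annotated as a transcribed pseudogene. The Klra and Klrb1 genes are close copies of each other and differ between BALB/c and the C57BL/6-based reference, so the split of reads among them is uncertain. Many of these genes sit in the NK gene complex on chromosome 6. Over the span of annotated Klr genes there, 128609227 to 131247362, 13 of 38 tested genes were higher in NK cells and 0 in T cells, an odds ratio of 45.2 (2-sided Fisher's exact test, p = 3.88e-16, across genes, which are not independent). The span was set by the Klr genes themselves, many of them NK identity genes, so an excess towards NK cells was built in. This test was not among those planned.

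Cytotoxic effector genes were higher in the NK cells. Among them Gzma, Gzmb and Prf1 are also in identity lists. Of 20 measured members, 7 were higher in NK cells and 0 in T cells (16 adjusted over the list alone, and 16 with the replicate block). All 20 had a positive log2 fold change, and camera gave adjusted p = 6.02e-21, and adjusted p = 0.333 with an estimated correlation. The size of the gap differed with the pool, with a median log2 difference of 3.09 in pool 1 and 1.55 in pool 2. Gzmf stood at 316 in NK cells against 8.81 in T cells in pool 1, but at 319 against 258 in pool 2. Beside Gzma and Gzmc, Gzmb, the granzyme that activates caspases, reached 2615 ± 917 against 187 ± 30.9 (log2 fold change 3.77, SE 0.33, limma adjusted p = 2.40e-04), and Prf1, the pore-forming perforin, 1659 ± 690 against 150 ± 99.6 (3.57, SE 0.47, adjusted p = 0.00317). Granzyme genes are close copies of each other, so reads of Gzmb to Gzmg can be split between them.

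Chemokine genes were also higher in NK cells, with 6 of 14 measured members past the threshold and 0 higher in T cells (11 adjusted over the list alone; camera adjusted p = 1.57e-10, and adjusted p = 0.352 with an estimated correlation). Xcl1, a ligand for cross-presenting dendritic cells, stood at 152 ± 38.6 against 10.2 ± 0.38. Ccl2, Ccl7 and Ccl9, which attract monocytes, had log2 fold changes of 4.75 (SE 0.78), 3.85 (SE 0.76) and 3.07 (SE 0.62). These 3 are also made by macrophages, and summed core macrophage markers were 1087 and 244 in the NK libraries against 270 and 29.4 in the T libraries. Chemokine receptors went mostly the other way, with 1 of 15 higher in NK cells and 5 higher in T cells (3 and 7 adjusted over the list alone, and 3 and 7 with the replicate block; camera adjusted p = 0.00242 towards T cells, and adjusted p = 0.333 with an estimated correlation). Ccr7, the receptor for homing to lymph nodes, was at 3.63 ± 0.62 in NK cells, and in T cells at 52.9 in pool 1 and 348 in pool 2.

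**Figure D2:**
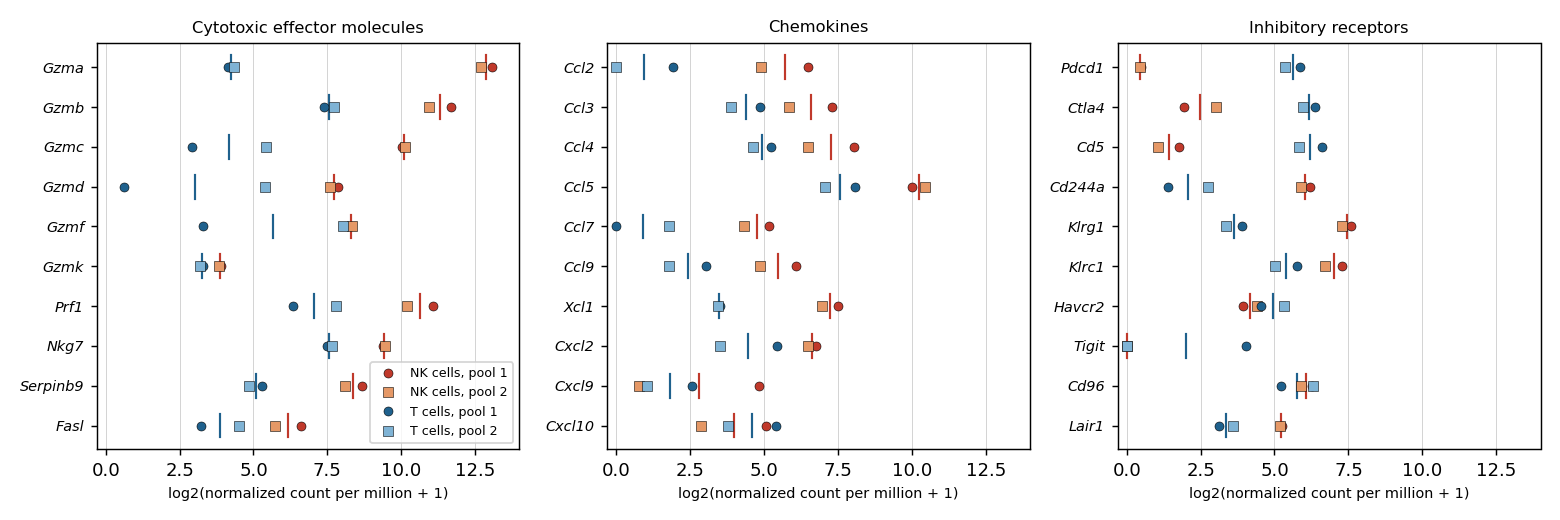
Cytotoxic, chemokine and inhibitory receptor genes in each library (points), as log2(normalized CPM + 1), with the mean of the 2 pools as a vertical bar. The genes shown of each list were picked after their values were seen and include genes that did not pass the threshold. Gzmb stood at 3263 and 1966 in NK cells against 165 and 208 in T cells, and Pdcd1 at 0.41 and 0.35 against 57.3 and 40.0.

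Inhibitory receptors split between the cell types. However, Cd244a and Klrg1 on the NK side and Cd5 on the T side are also in identity lists, which describe the sort. Of 20 measured members, 2 were higher in NK cells and 3 in T cells (6 and 7 adjusted over the list alone, and 6 and 7 with the replicate block; camera adjusted p = 0.599). Pdcd1, which encodes PD-1, had 2 reads in NK cells and 217 in T cells, a T to NK ratio of 124 with a counting interval of 33.8 to 1030 (log2 fold change -5.15, SE 0.61, limma adjusted p = 0.00158). Cd5, a negative regulator of T cell receptor signalling, differed by -4.80 (SE 0.56). Cd244a, the 2B4 receptor, stood at 65.2 ± 9.54 in NK cells against 3.66 ± 2.84, and Klrg1, a marker of terminal maturation, at 175 ± 26.6 against 11.5 ± 3.22. Costimulatory receptors were higher in T cells, with 6 of 17 past the threshold and 0 higher in NK cells (1 and 10 adjusted over the list alone, and 1 and 10 with the replicate block; camera adjusted p = 4.84e-08, and adjusted p = 0.352 with an estimated correlation). They included Icos, at 291 ± 205 against 20.4 ± 1.77, and Slamf1, at 76.9 ± 47.1 against 1.73 ± 0.44.

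Of 23 exhaustion and memory transcription factors, 2 were higher in NK cells (Eomes and Id2) and 4 in T cells (3 and 13 adjusted over the list alone, and 4 and 13 with the replicate block). On this list camera gave adjusted p = 0.0011 towards T cells, and adjusted p = 0.333 with an estimated correlation. Id2, a factor of innate lymphocyte development, stood at 1608 ± 128 against 641 ± 80.2. Tcf7, the memory-associated factor TCF-1, stood at 52.4 ± 28.7 in NK cells against 368 ± 281 in T cells, and Irf4 had 3 NK reads and a T to NK ratio of 40.6 (counting interval 13.5 to 200). Among 17 cytokine genes, 0 were higher in NK cells and 2 in T cells (2 and 4 adjusted over the list alone; 2 and 5 with the replicate block). These were Tnfsf8, at 77.5 ± 7.93 in T cells against 11.7 ± 5.57, and Tnfsf11, the RANK ligand, with 0 NK reads and at least 18.2-fold higher. Of 22 cytokine receptor genes, 1 was higher in NK cells and 4 in T cells (3 and 9 adjusted over the list alone; 4 and 8 with the replicate block). Il2rb, the shared IL-2 and IL-15 receptor chain, stood at 1389 ± 19.4 in NK cells against 559 ± 41.4, and Il7r at 28.8 ± 7.39 against 666 ± 183. Camera gave adjusted p = 0.0137 for cytokines and 0.00389 for their receptors, both towards T cells, and adjusted p = 0.382 and 0.333 with an estimated correlation. The cytokine call was lost without NK replicate 2 (adjusted p = 0.103) or T replicate 1 (0.108), and the receptor call without T replicate 1 (0.296).

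Genes of NK activating adaptors and proximal signalling went both ways, with 6 of 23 higher in NK cells and 3 in T cells (9 and 4 adjusted over the list alone; camera adjusted p = 0.078, and 0.00997 with the replicate block). Tyrobp, the adaptor DAP12, also expressed by myeloid cells, stood at 384 ± 6.46 in NK cells against 13.0 ± 12.8, and Sh2d1b1, an EAT-2 adaptor, at 44.1 ± 23.9 against 1.69 ± 1.61. Plcg1 and Lat, which relay T cell receptor signals, stood at 61.5 ± 25.9 and 165 ± 5.93 in T cells against 1.70 ± 0.10 and 16.7 ± 2.39. Of 12 genes of circulating NK maturation, 3 were higher in NK cells and 1 in T cells (5 and 3 adjusted over the list alone; 5 and 3 with the replicate block), with Klrg1, Itgam and Gzmb on the NK side and S1pr1 on the T side. Its camera adjusted p = 0.0261 became adjusted p = 0.377 with an estimated correlation and was lost without each of the 4 libraries in turn (NK replicate 1, 0.128; NK replicate 2, 0.0649; T replicate 1, 0.0784; T replicate 2, 0.287). Of 15 genes of ILC1 and tissue residency, 1 was higher in NK cells and 4 in T cells (1 and 7 adjusted over the list alone; 1 and 7 with the replicate block). Itga1, the collagen-binding integrin CD49a, stood at 115 ± 17.0 in NK cells against 22.3 ± 1.99, while Il7r and Il21r were higher in T cells. Camera gave adjusted p = 0.00242 towards T cells, and adjusted p = 0.377 with an estimated correlation, and the call was lost without T replicate 1 (0.523).

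**Figure D3:**
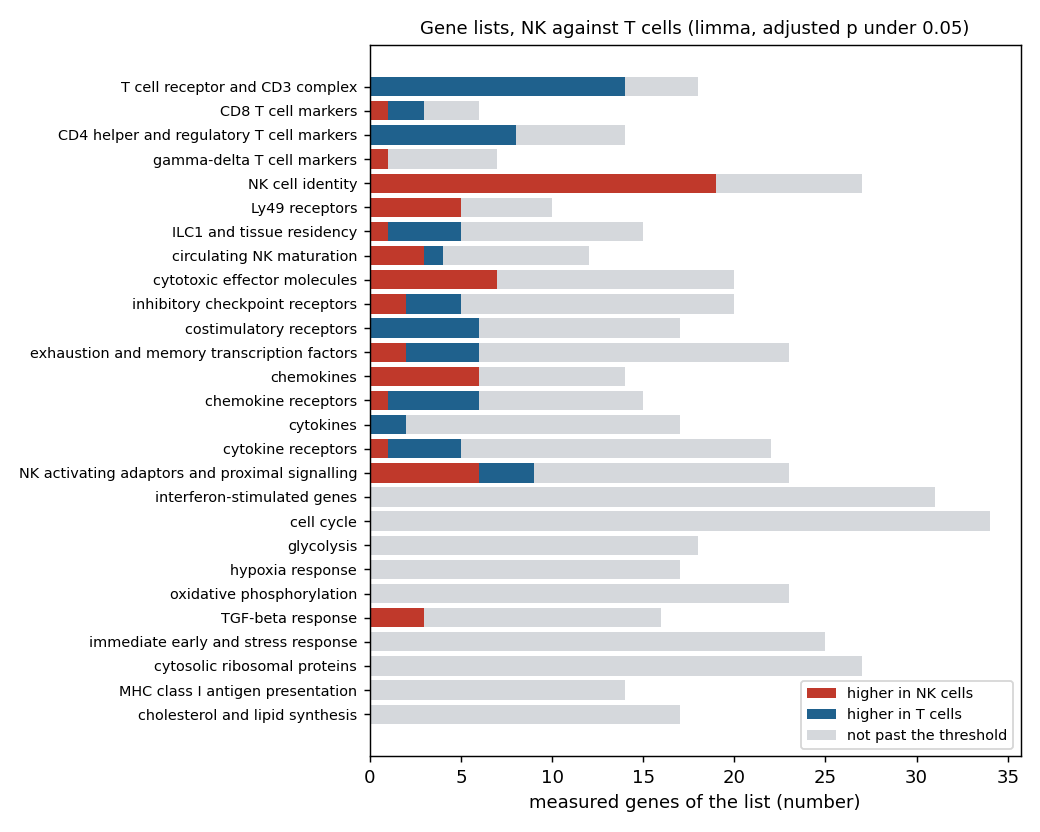
Number of measured genes per list that were higher in NK cells, higher in T cells or not past the threshold of the limma test, for the lists other than those of other cell types. The NK identity list had 19 of 27 genes higher in NK cells and the T cell receptor list 14 of 18 higher in T cells, while 0 genes of the interferon, cell cycle, glycolysis, hypoxia, oxidative phosphorylation, stress, ribosomal, class I and cholesterol lists passed.

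The programme lists other than the TGF-beta response had 0 members past the threshold by limma, and 0 by edgeR. Of 31 interferon-stimulated genes 0 passed (2 higher in NK cells and 5 in T cells at an unadjusted p under 0.05, 0 and 1 adjusted over the list alone, and 1 and 5 with the replicate block). Ifi47 stood at 188 ± 11.8 in NK cells and 332 ± 5.07 in T cells, adjusted p = 0.243. Camera gave adjusted p = 0.0392 towards T cells and adjusted p = 0.817 with an estimated correlation; without NK replicate 2 it was 0.807, and without T replicate 1 the direction turned (0.383). For 34 cell cycle genes (0 at an unadjusted p under 0.05), of which Top2a stood at 256 ± 111 against 218 ± 142, camera gave adjusted p = 0.0261 towards NK cells and adjusted p = 0.817 with an estimated correlation; the direction turned without NK replicate 1 (0.721), and without T replicate 2 it was 0.928. For 23 oxidative phosphorylation genes, such as Cox5a at 223 ± 39.0 against 151 ± 10.9, 2 were higher in NK cells at an unadjusted p under 0.05 and 2 with the replicate block, and 0 adjusted over the list alone. Camera gave adjusted p = 0.0248 towards NK cells, adjusted p = 0.352 with an estimated correlation, and 0.0647 with the replicate block. The other lists, in the order glycolysis, hypoxia, stress response, ribosomal proteins, class I presentation and cholesterol synthesis, had camera adjusted p of 0.115, 0.599, 0.0808, 0.377, 0.882 and 0.624. Their 18, 17, 25, 27, 14 and 17 measured members included 0, 1, 8, 2, 0 and 1 at an unadjusted p under 0.05, and 0, 0, 1, 0, 0 and 0 adjusted over the list alone. With the replicate block 0, 1, 5, 2, 0 and 1 passed. Without T replicate 1 glycolysis passed towards NK cells (camera adjusted p = 0.000174) and ribosomal proteins towards T cells (1.39e-05), and without T replicate 2 the stress response passed towards T cells (0.02). B2m, for example, stood at 4199 ± 60.6 against 3642 ± 672, and Ldha at 607 ± 242 against 485 ± 243. Of 16 genes of the TGF-beta response, Itga1, Eomes and Cd9 were higher in NK cells and 0 in T cells (3 and 1 adjusted over the list alone; 3 and 3 with the replicate block). This list's median log2 fold change was -0.18 and its mean 0.21, and camera gave adjusted p = 0.694.

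Markers of other cells were also measured, because the sort gate is not given in the sources used here. The macrophage and monocyte list summed to 5806 and 3492 in NK pools 1 and 2 and to 1769 and 843 in T pools 1 and 2, with Spp1 the largest member. Of 24 measured members, 6 were higher in NK cells and 0 in T cells (14 adjusted over the list alone; 16 and 0 with the replicate block; camera adjusted p = 5.83e-14, and adjusted p = 0.352 with an estimated correlation). Spp1, osteopontin, stood at 1436 ± 382 against 113 ± 128, Arg1, arginase 1, at 83.2 ± 29.0 against 2.20 ± 3.11, Cd14 at 27.3 ± 19.0 against 1.16 ± 0.86, and Itgam, also a marker of mature NK cells, at 133 ± 69.2 against 12.3 ± 8.34. The macrophage lysozyme gene Lyz2, named after its values were seen, did not pass (limma adjusted p = 0.321), at 510 and 130 in NK cells and 175 and 16.7 in T cells. Within each pool it was nonetheless higher in NK cells than in T cells. With the macrophage score as a covariate in the limma fit, an alternative chosen after seeing the data, 788 genes passed, 465 higher in NK cells and 323 in T cells, and 261 of the 282 genes were among them.

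**Figure D4:**
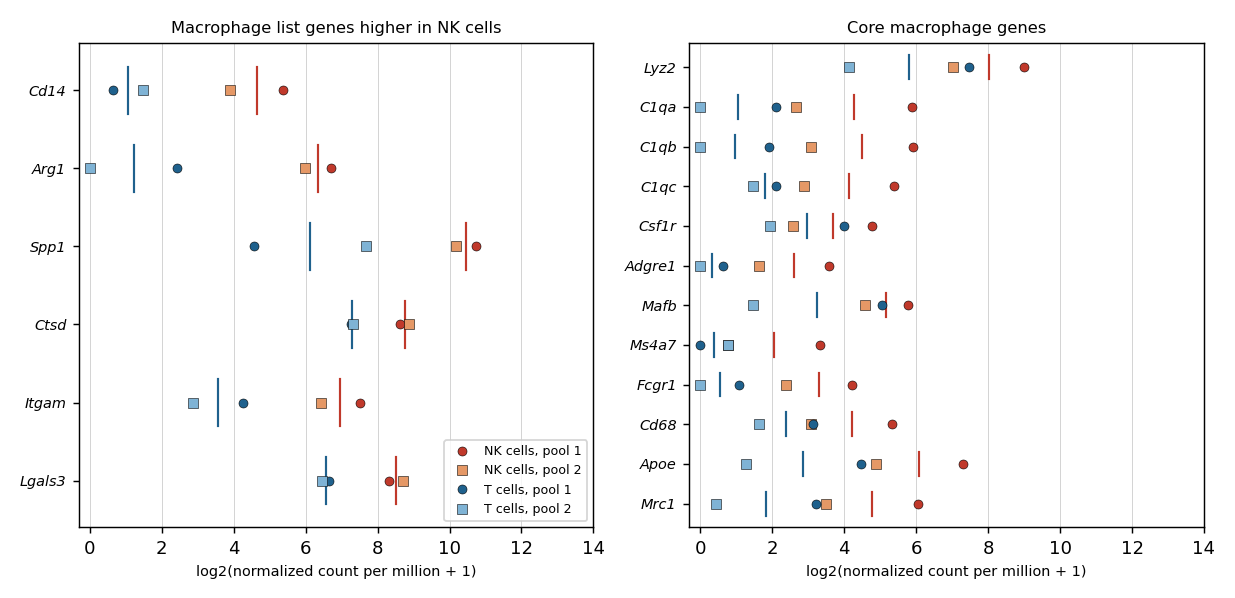
The 6 macrophage list genes past the threshold and 12 further core macrophage genes in each library (points), as log2(normalized CPM + 1), with the mean of the 2 pools as a vertical bar. Spp1 stood at 1706 and 1166 in NK cells against 22.6 and 203 in T cells, whereas Lyz2 in NK pool 2 (130) lay below that in T pool 1 (175). Within each pool Lyz2 was higher in NK cells than in T cells.

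The neutrophil list, with 0 of 7 members past the threshold by limma or edgeR (0 at an unadjusted p under 0.05; camera adjusted p = 0.624, and 0.012 towards NK cells without T replicate 1), summed to 108 and 84.7 in NK cells and 232 and 29.8 in T cells. In the dendritic cell and class II list, Itgax and Tcf4 were higher in NK cells and Ccr7 in T cells among 13 members (2 and 1 adjusted over the list alone). Camera gave adjusted p = 0.191, and 0.0206 towards NK cells without NK replicate 2 and 0.013 without T replicate 1. Of 10 CT26 and epithelial genes 0 passed by limma or edgeR (2 and 2 at an unadjusted p under 0.05, 2 and 1 adjusted over the list alone and with the replicate block; camera adjusted p = 0.599), and S100a6 stood at 766 ± 10.2 against 314 ± 94.6. Of 4 B cell genes 0 passed by limma or edgeR (0 at an unadjusted p under 0.05), and Ighm stood at 39.3 ± 22.2 against 39.0 ± 6.04. In the remaining lists, with 3 fibroblast, 1 endothelial, 4 mast cell and 6 erythroid and platelet genes measured, Fn1, Col1a2 (0 T reads, at least 17.9-fold higher), the mast cell protease gene Cma1 (0 T reads, at least 20.2-fold higher) and Pf4 (2 T reads, ratio 93.6, counting interval 25.6 to 778) were higher in NK cells. These 4 genes were also the ones past the threshold adjusted over each list alone, with Pecam1 added, which stood at 197 ± 72.0 against 77.4 ± 19.9 (limma adjusted p = 0.122, and 4.89e-04 with the replicate block). Cma1 is also in the NK identity list. Without Pf4 the erythroid and platelet list summed to 0 and 56.0 in NK pools 1 and 2, and to 0 and 6.38 in T pools 1 and 2. For the 6 erythroid and platelet genes camera gave adjusted p = 0.0111 towards NK cells, and adjusted p = 0.472 with an estimated correlation; it was lost without NK replicate 2 (0.822), T replicate 1 (0.119) or T replicate 2 (0.1).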

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

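The comparison of the 2 pools in this part was chosen after the results were seen. For 8 of 36 gene lists the median log2 difference between NK and T cells had opposite signs in the pools, with 1 NK and 1 T library in each. The difference between pools was not tested, and a median near 0 changes sign easily. The median moved from -0.719 in pool 1 to 0.000581 in pool 2 for gamma-delta T cell markers (difference 0.72), and from -1.25 to 0.107 for ILC1 and tissue residency (1.36). It moved from -0.137 to 0.698 for glycolysis (0.835), from -0.0392 to 0.21 for the hypoxia response (0.249), and from -0.472 to 0.0702 for the TGF-beta response (0.542). For cytosolic ribosomal proteins it went from 0.0631 to -0.388 (-0.451), and for cholesterol and lipid synthesis from 0.291 to -0.0877 (-0.379). Among these 8 lists the neutrophil list moved most, from -0.848 to 1.36 (2.21).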

How the results depend on the processing

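The macrophage covariate, the fit without ribosomal RNA genes, edgeR with the block, limma-voom and the edgeR fits without each library were chosen after seeing the data, unlike the others. None of the 282 genes that were tested under a setting changed direction in any of them. Their NK and T values did not overlap, so leaving out a library could not turn the direction. The number past the threshold was 999 with the replicate block (883 with edgeR and the replicate block), 788 with the macrophage covariate and 441 with the DESeq2 Wald test, where 2117 adjusted p-values were undefined. It was 38 without a trend in the spread model, 98 with a pseudocount of 0.1, 113 after quantile normalization and 91 tested against a 2-fold change. Other settings gave 246 to 368 genes. Without each library in turn limma called 0 to 0 genes, with 1 residual degree of freedom and the lone library assumed to vary like the other group, so all 72 named genes past the threshold lost that call; 752 to 1759 genes had an unadjusted p under 0.05. In edgeR the same fits called 330, 423, 470 and 514 genes without NK replicates 1 and 2 and T replicates 1 and 2, and they shared 224, 241, 265 and 259 of the 282. Of the 72 named genes, 47 were lost without the trend, 31 with the pseudocount of 0.1, 27 after quantile normalization and 25 against a 2-fold change. Why these counts differ was not tested. Each library left out removes a degree of freedom. That alone need not end the limma calls, since the replicate block fit also has 1 residual degree of freedom and called 999 genes.

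Of 32 gene lists, 18 passed with camera, 0 with an estimated correlation and 4 with fry, which tests each list on its own. The 4 were the T cell receptor (fry adjusted p = 0.0157), NK identity (0.0171), Ly49 (0.0276) and NK adaptor (0.0342) lists, the last not called by camera. The cytotoxic (fry adjusted p = 0.0949), chemokine (0.229), costimulatory (0.134) and transcription factor (0.16) lists did not pass with fry. With camera and a mean of at least 10, 12 of 29 passed, which ended the calls of chemokine receptors (0.0662), cytokines (0.108), the cell cycle (0.0522), oxidative phosphorylation (0.0603) and NK maturation (0.125), and left the erythroid and platelet list untested. Quantile normalization ended the interferon call (0.0516). Leaving out genes shared between lists of the same kind (identity, function, programme or other cells) ended that of NK maturation (0.077). Genes that function lists share with identity lists, such as Gzma in the cytotoxic list, stayed in. The macrophage covariate ended the calls of NK maturation (0.0815), transcription factors (0.0536) and oxidative phosphorylation (0.0987), and added those of the TGF-beta (0.00542) and stress responses (0.00292). Without each library in turn 15 to 16 passed. The replicate block ended the oxidative phosphorylation call and added that of NK adaptors, and changed no other list call. Reversed in direction were the cell cycle list without NK replicate 1 (adjusted p = 0.721; 3.91e-05 to 0.928 without each library in turn) and with the macrophage covariate (0.182), the interferon list without T replicate 1 (0.383; 4.97e-05 to 0.807 without each library in turn), the dendritic cell and class II list with the covariate (0.00554), and the gene Il1b with the covariate (log2 fold change -2.32); the cause was not tested. The macrophage list sum, higher in NK cells by 1.88 on the log2 scale, stayed higher at 1.35 to 2.48 under the other summaries and without each library in turn. The core macrophage markers alone were higher in NK cells by 2.51, and by 0.928 to 4.09 without each library in turn. Depth limits low genes, since 3 reads correspond to 1.06 to 1.65 normalized CPM in a library.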

Other observations

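All tests in this part were chosen after the results were seen. Genes also differed between the pools. In a fit with cell type and pool as terms, which has 1 residual degree of freedom, 101 genes were higher in pool 1 and 151 higher in pool 2 (limma adjusted p under 0.05). That fit averages the change over NK and T cells, and 244 of the 252 genes called moved in the same direction in both. Calling genes on that average favours such agreement. Across all genes tested the pool differences of NK and T cells correlated at 0.161. The SE of that fit did not reflect disagreement between the cell types, so a large change in 1 of them could suffice. Gzmf was called (SE 0.30, limma adjusted p = 3.22e-11) with little change in NK cells. A fit of pool alone called 0 genes with limma, and 500 had an unadjusted p under 0.05. Of 13 dendritic cell and class II genes 5 were higher in pool 1 and 0 in pool 2 (camera adjusted p = 2.21e-14, and adjusted p = 0.617 with an estimated correlation). H2-Aa stood at 138 and 60.0 in the NK and T libraries of pool 1 against 10.6 and 12.4 in pool 2. Core macrophage markers summed higher in pool 1, at 1087 and 270 against 244 and 29.4. Of 31 interferon-stimulated genes 8 were higher in pool 1 and 0 in pool 2 (camera adjusted p = 1.12e-16, and adjusted p = 0.617 with an estimated correlation). Rsad2, an antiviral enzyme, stood at 82.6 and 144 against 39.7 and 13.8. Of 34 cell cycle genes 5 were higher in pool 1 and 0 in pool 2 (camera adjusted p = 1.61e-10, and adjusted p = 0.617 with an estimated correlation). Pool 2 had higher Nrarp, a Notch target, at 211 and 24.4 against 40.7 and 0.55, and higher Bbc3, a p53 target, at 206 and 161 against 74.8 and 34.1. Gzmf, a granzyme, stood in T cells at 258 in pool 2 against 8.81 in pool 1, and in NK cells at 319 against 316. The genes of this paragraph were chosen after their values were seen.

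Of 16 TGF-beta response genes 3 were higher in pool 2, namely Smad7, Skil and Ski, which feed back on that signalling, and 1 in pool 1, namely Tgfbi, at 87.0 and 49.0 against 15.2 and 7.09. Camera gave adjusted p = 0.000142 towards pool 2, and adjusted p = 0.617 with an estimated correlation. Smad7 stood at 255 and 329 in the pool 2 NK and T libraries against 44.7 and 118 in pool 1 (log2 difference 1.98, SE 0.30). Dilution of lymphocyte RNA by other cells in pool 1 would raise the cells' own identity genes in pool 2 as much. Their median changes were -0.307 (interquartile range 0.559) for NK identity genes and -0.191 (interquartile range 0.673) for T cell receptor genes. The smallest rise of the 3 genes was 2.08 in NK cells and 0.956 in T cells. These 3 were chosen for rising in the same libraries, so their lead over the identity genes was fixed in advance. The whole TGF-beta list moved by medians of 0.845 in NK cells and 0.341 in T cells. Only the lack of a rise in the identity genes, which were not chosen by pool, argues against dilution as the whole cause. Handling or sequencing batch and the mice themselves cannot be told apart for the 252 genes, because the labels give no batch that cuts across the pools.

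Trbc1 and Trbc2, the T cell receptor beta constant genes, were read in the NK libraries at 72.7% and 52.0% (Trbc1) and 22.4% and 17.7% (Trbc2) of the T level in pools 1 and 2. In comparison, 11 T cell genes such as Trac, Cd3e and Cd8a stood at 0% to 4.54% of the T level where the T library held enough reads, with a highest upper 95% bound of 6.77%, so T cells in the NK gate would leave Trbc1 and Trbc2 far lower than their lowest lower bound of 16.1%. A split of reads between the near-identical pair is argued against as the whole cause by their sum, whose lower bound was 26.0%. Whether the transcripts are rearranged stays open, since Trbv segments had 0 NK reads against 19 and 11 T reads, and the upper bound of Trbv reads per Trbc read was 46.4% and 143% of that in T cells. For Cd3g, at 26.6% and 6.20% of the T level, the lower bound in pool 2 was 4.43%, so T cells in the gate cannot be told apart from NK expression there; a candidate explanation for Trbc1 and Trbc2 is transcription of unrearranged constant regions in NK cells, which was not tested directly.

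The 6 macrophage list genes past the threshold (Spp1, Arg1, Cd14, Itgam, Ctsd and Lgals3) may be carried by macrophage RNA in the NK libraries or be expressed by NK cells. With the macrophage score as a covariate all 6 stayed higher in NK cells. The log2 fold changes of Arg1 and Itgam went from 5.14 to 3.55 and from 3.39 to 2.24. Those of Cd14 and Lgals3 went from 3.58 to 3.49 and from 1.95 to 2.01. For Ctsd and Spp1 they went from 1.47 to 1.60 and from 4.35 to 5.83, and for Lyz2 from 2.21 to -0.31 with the covariate. That fit has 1 residual degree of freedom, and the 6 genes were chosen by the test of the same 4 libraries. Between NK pool 2 and T pool 1, whose core macrophage sums were 244 and 270, the lowest ratio of the 6 was 3.12 (lower bound 2.74). A choice by the NK to T test fixes that direction, however. Cd14, a core marker itself, had a ratio of 25.1, from 39 reads against 1 (counting interval 4.25 to 1020). Macrophage RNA and expression by NK cells therefore cannot be told apart for these 6 genes, because no value here is free of that choice.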
